A study of Mus musculus with 6 samples.

How the data were processed

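Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in blood monocytes of mice given diphtheria toxin. The series title speaks of histone modifications, while the sample titles, design text and protocols describe ATAC-seq, and the peaks were read as ATAC-seq peaks on that ground. The DTR group holds 3 libraries from mice of the PF4cre-iDTR genotype and the WT group 3 libraries from wild-type mice. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were permeabilised with digitonin before the Tn5 reaction and libraries were sequenced in pairs on a NovaSeq instrument. Per the submitters' processing notes, fastp, Bowtie, Bowtie2 (version 2.4.4) and MACS2 were used. Their parameters and any shift of reads for the transposase offset are not given in the sources used here, and neither is the genome build.

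The deposited data are 6 lists of broad peaks, 1 per library, so peaks were called by the authors on each library alone. Each list gives a peak's position, the authors' score, the fold enrichment (a ratio) over the caller's background, and the −log10 of its p-value and q-value. The deposited score equals 10 times the −log10 q, truncated, for 99.9% of the peaks of each library after rounding. The smallest deposited −log10 q of a library lay between 1.01 and 1.03. The lists hold no read counts, so the depth of each library is unknown and no interval that needs counts can be given. Score, fold and −log10 values are the authors' own and were used to describe, rank or filter peaks within a list.

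Coordinates are those of the deposited lists, counted from 1. Gene names came from a RefSeq gene table of GRCm38. Its fit to the peak lists was checked by counting, per chromosome, the protein-coding genes with a shared peak within 100 bp of a gene end. The share was 34.2% to 61.1% over 20 chromosomes, against 3.93% to 15.1% after moving the genes by 5 or 20 kb. No coordinates of that table are printed. It gives neither strand nor exons, so transcription start sites could not be used as planned. A gene end here means a window of 1 kb on each side of either end of a protein-coding gene, and regions were classed as gene end, gene body or intergenic. No genome sequence was used, so the planned test of 17 transcription factor motifs was not run.

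Peaks that overlapped or touched were merged over the 6 lists, and a library had a region when at least 1 of its peaks fell in it. A DTR-only region had a peak in all 3 DTR and in 0 WT libraries, and a WT-only region the reverse. These counts were set beside the same count for each of the 20 sets of 3 libraries, 18 of which mix both groups. Values per library were compared by an exact two-sided permutation test. With 3 libraries against 3 its smallest p is 0.1. The labels do not say whether the libraries came from separate animals or pools, so the p-values of this test measure only the spread between these libraries. Similarity was the base-pair Jaccard index, shared length over joint length. Locations were compared by Fisher's exact test, two-sided, over regions, which are not replicates.

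For each of 24 gene lists (11 of cell types, 12 of pathways and 1 of loci used in the transgenes), DTR-only minus WT-only regions within 10 kb of the gene bodies were compared with 10000 random lists in a two-sided gene permutation test. Random genes were drawn with replacement and matched on the number of regions per gene, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. These p-values take genes as units, so they measure no spread between libraries or animals. Mx1, Mx2, Rigi and Par1 matched no gene of the table. The comparisons between groups, gene lists, the naming rule and most alternative settings were fixed before the data were examined. The comparison by chromosome, that with regions of 3 libraries of both groups, the settings of regions of at least 200 bp, of single gene ends and of equal length with 50 kb together, and most closing tests were added later. The rule named, in each direction, the 10 regions with the highest value of their lowest fold that lay in or within 50 kb of a gene, 1 per gene. It also named the 5 genes with the highest ranked group-only end, up to 3 genes per list, and 9 genes fixed by name. Alternatives were a q of at most 1e-05, lists of equal length (each cut to its strongest peaks by −log10 p), autosomes alone, and each library left out. Others changed the overlap, the joining of peaks, the number of libraries required, the gene windows and the list test. On simulated lists of 92757 regions, 200 of 200 seeded DTR-only and 100 of 100 seeded WT-only regions were recovered. Seeded regions were placed in exactly the libraries of 1 group, so their recovery was fixed by construction. In all, 379 simulated regions were DTR-only, unseeded ones included, against at most 196 in a mixed set. A list seeded with 12 regions had an adjusted p of 0.0048, and 0 other lists passed. Merging and the Jaccard index were checked against bedtools (version 2.31.1), with 92757 regions from both. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.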

Results

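Chromatin accessibility was compared between monocytes of thrombocytopenic and control mice. In PF4cre-iDTR mice, the receptor for diphtheria toxin is expressed in cells in which the promoter of Pf4, a platelet chemokine gene, has driven Cre, so that the toxin depletes megakaryocytes and platelets. Wild-type mice given the toxin served as controls. The data comprised 3 DTR and 3 WT libraries, each with its own list of broad peaks of open chromatin and no read counts.

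Open chromatin at monocyte genes was shared by both groups, as it was at most genes. Of 21883 protein-coding genes, 12910 (59.0%) had a peak at a gene end in every library. All 15 genes of the classical monocyte list and 18 of 19 of the non-classical list had one. The same held for 33 of 33 myeloid transcription factors and 22 of 22 antigen presentation genes, and lists not tied to monocytes were about as high, with 26 of 27 for oxidative phosphorylation and 25 of 26 for cell cycle. Among markers of other blood cells the numbers were 13 of 14 for stem and progenitor cells, 14 of 18 for macrophages, 11 of 13 for dendritic cells and 9 of 15 for neutrophils. They were 8 of 17 for megakaryocytes and platelets, 6 of 12 for B cells, 7 of 16 for T and NK cells, 6 of 15 for erythroid cells and 0 of 12 for basophils, mast cells and eosinophils. Of 92757 merged regions, 68712 had a peak in all 6 libraries.

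The genes fixed by name had no group-only region. Within 10 kb of Csf1r, the receptor for the macrophage growth factor CSF-1, 7 of 10 regions were present in all 6 libraries. At Spi1, which encodes the myeloid factor PU.1, the number was 12 of 13. It was 3 of 6 at Ly6c2 and 3 of 3 at Ccr2, both classical monocyte markers, and 8 of 9 at Cx3cr1 and 10 of 11 at Nr4a1, both linked to non-classical monocytes. At Pf4 (1 of 1), its neighbour Ppbp (2 of 2) and Gt(ROSA)26Sor (2 of 2), a common insertion site of transgenes, every region was present in all libraries.

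Each DTR list was longer than each WT list. The DTR libraries had 82392 ± 1418 peaks (SD, n = 3) and the WT libraries 78835 ± 1428 (SD, n = 3), a difference of 3557 with an exact permutation p of 0.1, the smallest this design allows. The peaks covered 49.4 ± 1.14 Mb in DTR and 46.0 ± 1.95 Mb in WT (SD, n = 3; exact permutation p = 0.1). Their median width was 485 ± 10.4 bp and 474 ± 21.5 bp (exact permutation p = 0.4). Without read counts, a difference in sequencing depth between the groups cannot be separated from these values.

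On average, libraries of 1 group overlapped slightly more than libraries of different groups. The mean Jaccard index was 0.831 within DTR, 0.816 within WT and 0.812 between groups. Within minus between groups the difference was 0.0115, against at most 0.00634 in the other splits of the 6 libraries (one-sided exact permutation p = 0.1). WT library 1 was an exception, with an index of 0.823, 0.825 and 0.827 with the DTR libraries and of 0.813 and 0.820 with the other WT libraries. Its peaks covered 47.7 Mb, against 43.8 and 46.4 Mb in the other WT libraries and 48.1 to 50.1 Mb in DTR. The index can fall where covered lengths differ, so the effects of group and of covered length on it cannot be told apart here.

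**Figure D1:**
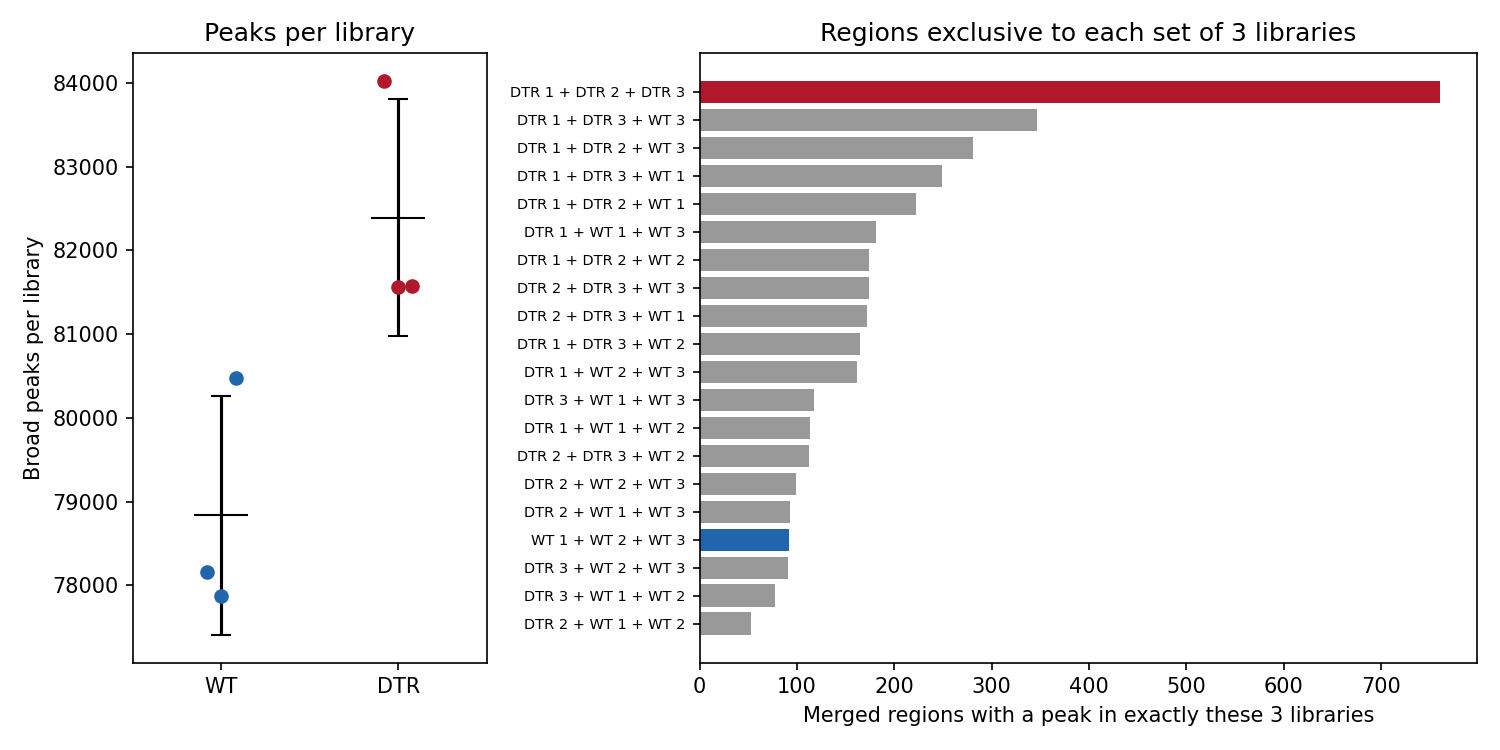
Left, broad peaks per library (points, with the mean and SD of 3 libraries per group); the axis does not start at 0. Right, the number of merged regions with a peak in exactly 3 given libraries, for the 20 sets of 3: 761 for DTR (red), 92 for WT (blue) and at most 347 for mixed sets (grey).

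The DTR libraries shared 761 regions that no WT library had, and the WT libraries shared 92 that no DTR library had. The highest count of the 18 mixed sets was 347, and 3 of them lay below the WT count. The balance of the groups depended on list length. With lists of equal length there were 490 DTR-only and 356 WT-only regions, against at most 202 in a mixed set, so the DTR-only share was 57.9% in place of 89.2%. Of the 761 DTR-only regions, 472 stayed DTR-only with lists of equal length, and 75 of the 92 WT-only regions stayed WT-only. The cut takes more peaks from the longer DTR lists. Regions that became WT-only only after it lay in merged regions with a DTR peak in the full lists, so the count of 356 is partly made by the cut.

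Group-only regions were narrow and weak by the authors' folds, and regions shared by 3 libraries of both groups were alike in this. The median width was 232 bp for DTR-only and 221 bp for WT-only regions, against 659 bp for regions in all libraries, and the median of the lowest fold was 3.03, 2.70 and 5.14. Among regions of 3 libraries of both groups, 38.5% were under 200 bp, against 39.7% of DTR-only and 43.5% of WT-only regions, with a median lowest fold of 2.86. The highest ranked DTR-only region with a gene nearby lay 7838 bp from D430019H16Rik (chromosome 12, 105445877 to 105446018), with folds of 6.14, 6.51 and 6.38 in the 3 libraries. The next lay 3485 bp from Snrpb, a spliceosome protein gene (chromosome 2, 130167990 to 130168151), and inside Ncoa3, a nuclear receptor coactivator gene (chromosome 2, 166060075 to 166060286). Regions inside Prpsap2, Atrx (a chromatin remodeller), Zfp318 and Tdrd3, and near Gad1, Gm19802 and Gm21188, completed the 10, with lowest folds from 5.23 to 5.72. Among WT-only regions, the highest ranked lay inside Pan3, a subunit of a deadenylase (chromosome 5, 147497896 to 147498043; folds 6.92, 6.17 and 6.69), and inside Galnt7 (chromosome 8, 57574531 to 57574695). Regions inside Gprasp2, Tpr, Dvl2, Faim2, Ptprk and Ttll4, near Adpgk, and at an end of Aplp1 followed, with lowest folds from 4.14 to 5.30. All 10 named regions of each direction stayed group-only with lists of equal length. They were chosen for high folds and the cut removes the weakest peaks, so this result was largely fixed by the selection.

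Group-only regions were less often at gene ends than regions of all 6 libraries, as were regions of 3 libraries of both groups. Gene ends held 6.18% of DTR-only and 8.70% of WT-only regions, against 19.4% of regions in all 6 libraries (Fisher's exact test, p = 4.48e-25 and 0.00777). Regions shared by 3 libraries of both groups had 6.52% at gene ends, and DTR-only regions did not differ from them detectably (odds ratio 0.943, Fisher's exact test, p = 0.803). DTR-only minus WT-only was −2.52 percentage points (Fisher's exact test, p = 0.366). This difference was −5.57 points with lists of equal length (p = 0.00325), −4.54 without DTR library 1 (p = 0.00915) and 0.616 without WT library 3 (p = 0.878), each by Fisher's exact test.

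In a comparison by chromosome, added after the data were examined, X and 16 held more DTR-only regions than shared regions would give. Chromosome X held 43, or 5.65% of DTR-only against 2.27% of regions in all libraries (odds ratio 2.58, adjusted p = 2.61e-06 over 20 chromosomes, Fisher's exact test), and 3 WT-only regions. Chromosome 16 held 47, or 6.18% against 3.59% (odds ratio 1.77, adjusted p = 0.00407, Fisher's exact test), and its share of WT-only regions was alike, at 6.52% (6 of 92). Against regions shared by 3 libraries of both groups, the odds ratio was 2.64 for X and 1.45 for 16 (Fisher's exact test, p = 4.78e-06 and 0.0430). Outside the 3 loci below, X held 20 of 738 DTR-only regions (2.71%), against 2.27% of regions in all libraries (Fisher's exact test, p = 0.385). No excess was detected there, but the loci were chosen for their values, so this cannot place the whole excess at them. Peaks on X numbered 1952 ± 28.3 in DTR and 1808 ± 35.4 in WT libraries (SD, n = 3; exact permutation p = 0.1).

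Of the 43 X-linked DTR-only regions, 23 lay within 2 kb of 3 long noncoding RNA genes, which were chosen after their values were seen. Firre, which takes part in the organisation of the inactive X chromosome, held 14 (between 50566435 and 50623425), with 17, 17 and 18 peaks in the DTR libraries and 2 in each WT library. 4933407K13Rik, at the macrosatellite Dxz4, held 7 (between 75729683 and 75759768), with 10, 10 and 8 peaks against 1 in each WT library. Xist, whose RNA silences the inactive X of female cells, held 2 (between 103481323 and 103484339), with 4, 3 and 3 peaks against 1. These loci held 0 WT-only regions. Regions on the short arm of Y had peaks in all libraries, numbering 15, 15 and 13 in DTR and 16, 18 and 17 in WT. The labels do not give the sex of the mice. On autosomes alone there were 718 DTR-only and 89 WT-only regions, against at most 337 in a mixed set.

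**Figure D2:**
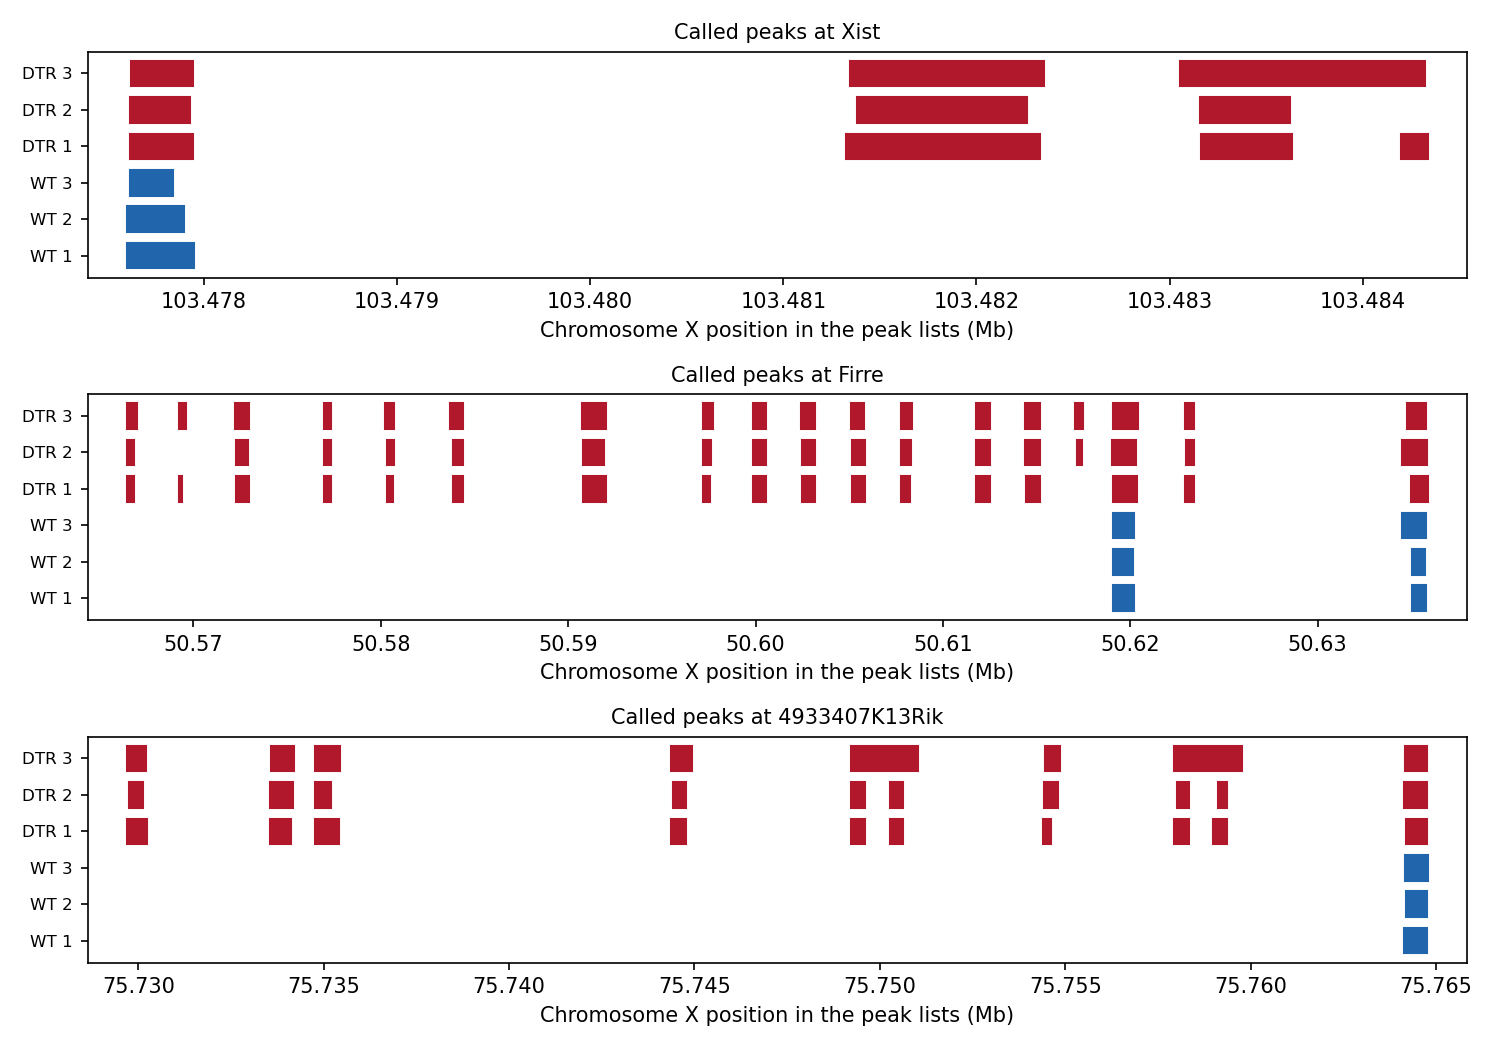
Peaks called in each WT (blue) and DTR (red) library at Xist, Firre and 4933407K13Rik, by position on chromosome X in Mb. The DTR libraries have 17 or 18 peaks at Firre and the WT libraries 2.

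At gene ends, 29 genes had a peak in all DTR and no WT library, and 4 the reverse, against at most 12 in a mixed set. The highest ranked DTR-only ends belonged to Mcoln3, a cation channel gene (folds 4.68, 5.29 and 4.57), Olfr1033, Chst1, Cd59a, which encodes a complement inhibitor, and Epgn, which encodes a growth factor. The 4 WT-only ends were those of Mgat3, Sapcd1, Sstr3 and Cabp7, with lowest folds from 2.32 to 2.78. The DTR-only count stayed above every mixed set in 12 of 14 alternative settings and not in the other 2. With lists of equal length 14 genes were DTR-only and 22 WT-only, against up to 24 in a mixed set, and with an overlap of 500 bp 26 were DTR-only against up to 36.

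None of the 24 gene lists passed the threshold, and 0 had an unadjusted p under 0.05 in the gene permutation test against matched random lists (0 also passed by Fisher's exact test). The smallest gene permutation p was 0.0562 (adjusted p = 1), for stem and progenitor genes. Their loci held 3 DTR-only regions, 2 in or near Erg and 1 in Myb, both transcription factor genes of blood progenitors. With lists of equal length the direction turned, to 2 DTR-only and 4 WT-only regions (gene permutation p = 0.0972), and the Myb region was no longer DTR-only. With the full lists these loci held 0 WT-only regions. All 4 therefore lay in regions with a DTR peak in the full lists, and the turn is made by the cut. The histone modifying enzyme list held 3 DTR-only regions, 2 in Smyd3 and 1 in Kdm5a, and 1 WT-only region in Hdac7 (gene permutation p = 1). Coagulation genes held 2 DTR-only regions, near Plat and F2rl1 (gene permutation p = 0.409), and myeloid transcription factors 2, in Bach2 and near Runx3 (p = 0.723).

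Most other lists held 1 DTR-only region each. Among cell types these lay in Fli1 for megakaryocytes and platelets, in Gata1 for erythroid cells, in Blk for B cells, near Retnlg for neutrophils, in Zbtb46 for dendritic cells and near Itgal for non-classical monocytes. Among pathways they lay near Oas1a (interferon response), near Tgfb3 (TGF-beta signalling), in Fcgr2b (phagocytosis), in Cd74 (antigen presentation), near Itgal (platelet binding), near Cox5a (oxidative phosphorylation) and in Ccnd3 (cell cycle). The lists of classical monocytes, macrophages, T and NK cells, basophils with mast cells and eosinophils, inflammatory cytokines, glycolysis and transgene loci held 0 group-only regions. Few group-only regions fell in each list, which limits what this test can detect.

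**Figure D3:**
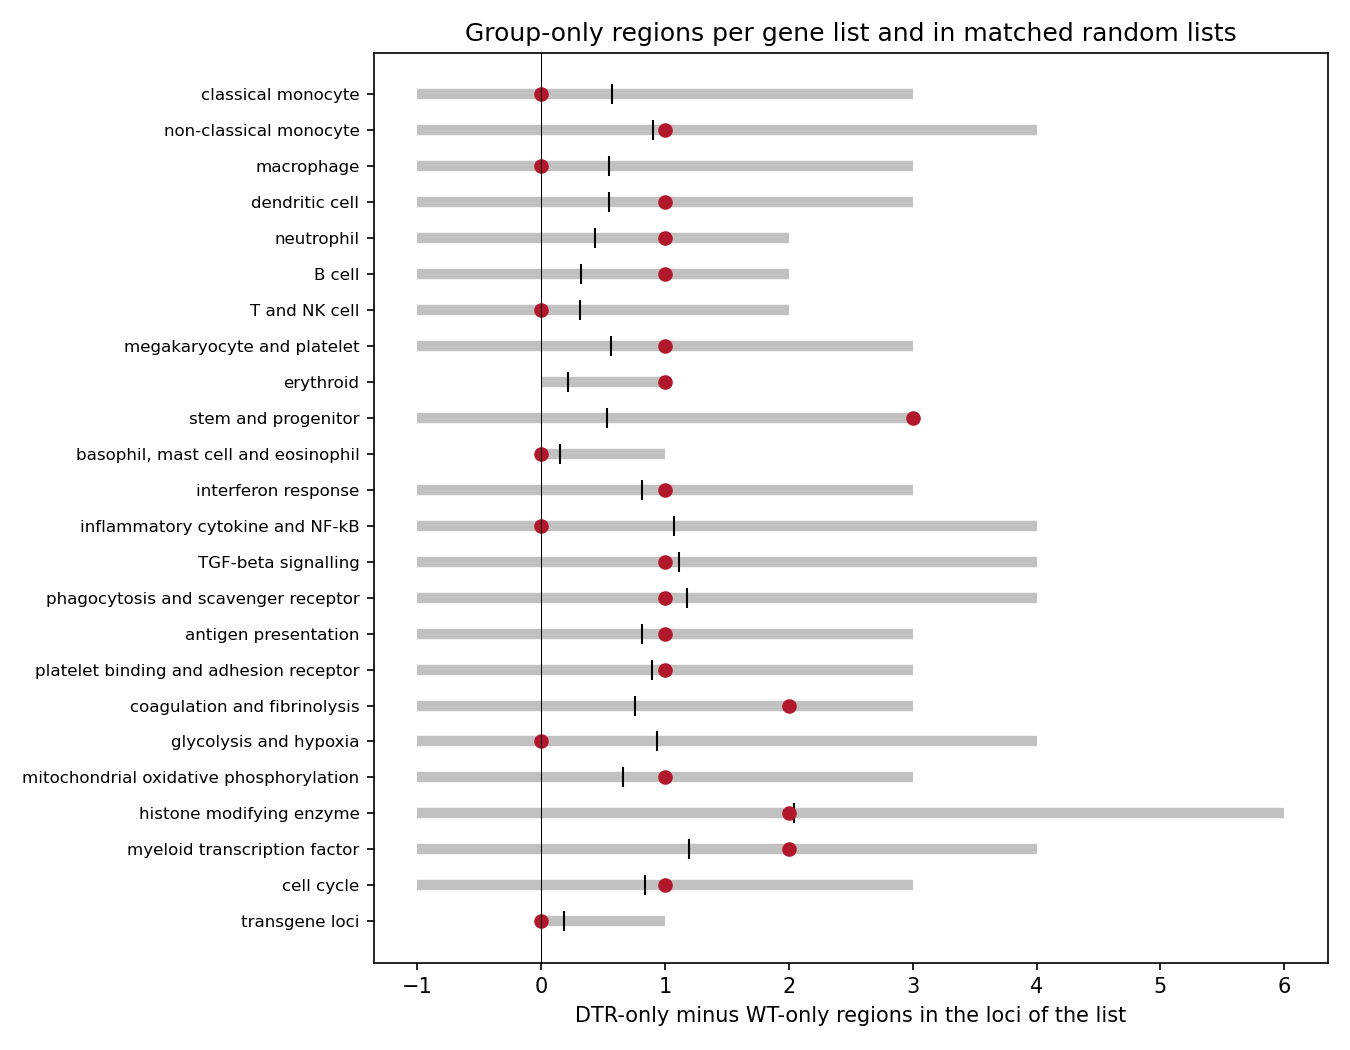
DTR-only minus WT-only regions within 10 kb of the genes of each of 24 lists (red points), with the mean (ticks) and central 95% (grey bars) of 10000 matched random lists. Each point lies inside its grey bar.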

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

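The alternatives with regions of at least 200 bp, with the lower or upper gene end alone, and with equal length and 50 kb together were chosen after the data were seen, and the others before. Of 106 alternative values over 23 settings, 67 kept their direction and side of the threshold, or stayed within 1.5 times of a count. In every setting run, the difference in peaks per library and the Jaccard difference kept their sign. In the planned settings 0 gene lists passed, and with lists of equal length and loci of 50 kb together 1 did, interferon response (gene permutation, adjusted p = 0.0192). With 3 libraries per group no p for the peak and Jaccard differences can pass 0.05, so their p-values say nothing about stability. With lists of equal length, DTR-only regions numbered 490, WT-only regions 356, genes with a DTR-only end 14 and with a WT-only end 22, and the gene end share differed by −5.57 points. That setting fixes the number of peaks, so it gives no value for it, and it removes more peaks from the DTR than from the WT lists. At a q of at most 1e-05, WT-only regions numbered 61 and genes with a WT-only end 1. With 2 of 3 libraries sufficing, which admits more regions by construction, the 4 counts were 2517, 582, 88 and 22. A mixed set then reached up to 1760 regions and 59 genes. Windows of 2.5 kb gave 8 genes with a WT-only end and upper coordinate ends alone 2. Regions of at least 200 bp numbered 459 (DTR-only) and 52 (WT-only). Leaving out 1 library loosens the definition: DTR-only regions then numbered 1124 to 1440, WT-only regions 175 to 294, and genes with such ends 41 to 53 and 6 to 17. In these settings the highest region count of any other set of libraries was 569 to 807 beside DTR-only and 811 to 1027 beside WT-only regions. The gene end share then ranged from −4.54 (without DTR library 1) to 0.616 points (without WT library 3, reversed). The cause was not tested where none is given. Libraries with the same number did not clearly deviate together (correlations −0.00277, 0.0144 and −0.00117, against −0.0140 to 0.0152 for different numbers). The check gave no sign of pairing, but with 3 libraries per group and present or absent calls it cannot exclude it. With a replicate block the peak difference was 3557 (exact sign-flip p = 0.25, the smallest possible), and the counts were equal by construction. The block was not run for locations and gene lists, and the motif tests were not run. Depth is unknown, so absence of a peak cannot be told from too few reads.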

Other observations

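The tests of chance splits of regions and gene ends, of X-linked regions, of other cell types, of Y-linked ranks, of region clusters, of the transgene neighbourhoods, of the second interferon list and of 50 kb with lists of equal length were chosen after the result was seen. DTR-only regions formed 8 clusters of at least 3 regions with gaps of up to 50 kb. Clusters rise with the number of regions, so 761 regions were drawn 1000 times from the 2882 regions shared by 3 libraries of both groups, which form 57 clusters in all. These draws gave 1.56 clusters on average (central 95% 0 to 4; permutation p = 0.001, the smallest they can give). Outside Firre (14 regions), 4933407K13Rik (7) and Xist there were 6, against 1.41 (0 to 4; permutation p = 0.003), but with lists of equal length 1 was left, against 0.192 (0 to 1; permutation p = 0.174). Fewer regions form fewer clusters, so the latter test decides little. The 6 lay at A730004F24Rik (4 regions, all still DTR-only with lists of equal length), at Gm40831, on chromosome 13 (99803724 to 99843014), at Tmem108, at Oas1h, Oas1g, Oas1a and Oas1d (3 regions each, 2 still DTR-only), and at Hspbap1 and Parp14 (3 regions, 0 still DTR-only). The cluster at 99803724 to 99843014 overlaps a cluster of 3 regions shared by libraries of both groups (99837890 to 99851908), so calls there also varied within the groups. The largest cluster among all 2882 regions held 6. Against 0.820% of all regions, DTR-only regions made up 0.870% (1 of 115) within 1 Mb of Gt(ROSA)26Sor and 0.795% (4 of 503) within 5 Mb. At Pf4 they made up 2.74% (2 of 73) and 1.69% (4 of 237; Fisher's exact test, p = 0.121 and 0.132), counts too few to decide.

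The DTR libraries shared more regions alone than any other 3 libraries. Longer DTR lists do not account for this in full, since with lists of equal length 490 DTR-only regions stood against at most 202 in a mixed set. The imbalance towards DTR was smaller in that setting, but the cut itself makes WT-only regions by removing DTR peaks. X-linked regions are too few to account for the DTR-only count: 43 of the 761 lay on X, which left 718 on autosomes. Cells of another type in the DTR libraries may contribute and stay open: the smallest adjusted p of their 9 marker lists was 1, but 74 of the 132 marker genes had an end peak in every library, which would hide a small share. Platelet depletion, sex composition and sequencing depth also stay open, as the design does not separate them. The 10 splits of the libraries into 3 and 3 are too few for a share under 0.05: the real split gave 853 group-only regions and the highest other 400 (1 of 10 as large), 33 and 15 group-only gene ends (1 of 10), and 0 and 0 gene lists (10 of 10).

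The 23 DTR-only regions at Firre, 4933407K13Rik and Xist lie at loci tied to the inactive X chromosome. Longer DTR lists do not account for them, since 22 of the 23 stayed DTR-only with lists of equal length. A candidate explanation is that the DTR libraries contain cells of female mice beside male cells, and the WT libraries male cells alone, in which case sex would differ with the group on autosomes too. Among regions of all libraries, ranked by fold within each library, the median percentile of 12 Y-linked regions was 44.5, 57.0 and 51.9 in DTR and 62.7, 64.8 and 61.9 in WT (highest DTR minus lowest WT −4.85; exact permutation p = 0.1, the smallest possible). Of the 12 regions, 4 ranked lower and 0 higher in every DTR library, and 9 had a lower DTR mean, but by their strongest region only 1 of 4 Y-linked genes ranked lower throughout, so the explanation stays open: Kdm5d did (72.4 ± 6.34 against 93.6 ± 0.557, SD, n = 3), but Eif2s3y (96.0 against 97.6), Uty (73.1 against 73.7) and Ddx3y (90.3 against 89.1) did not separate the groups.

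Within 50 kb the interferon response list came closest to the threshold without passing it (gene permutation p = 0.0026, adjusted p = 0.0624 over 24 lists), passed it with lists of equal length (p = 0.0008, adjusted p = 0.0192), and had an adjusted p of 1 within 10 kb in every setting of that test. Within 50 kb of its genes lay 9 DTR-only and 0 WT-only regions, near Cxcl9, Gbp2, Gbp5, Ifit1, Ifnar2, Oas1a, Oasl1 and Oasl2. Only 1 of the 9 regions lay within 10 kb of a listed gene, at 7523 bp from Oas1a, and none inside one. Longer DTR lists do not account for the counts within 50 kb. With lists of equal length the net stayed at 7, above the random interval of −4 to 3. Whether interferon response genes as a class gained regions could not be decided: a second list of 48 such genes, compiled after the first result was seen, gave a gene permutation p of 0.806 within 50 kb. That list left out Parp14, Parp9 and Dtx3l because a cluster had been seen there; with them p was 0.159, and 0.921 with lists of equal length. With all genes of both lists, including those that raised the question, p was 0.0032, and 0.0292 with lists of equal length.

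Narrow regions of high fold (under 200 bp, lowest fold of at least 4) made up 9.73% of group-only regions and 8.71% of regions shared by 3 libraries of both groups (Fisher's exact test, p = 0.375).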
